A study of Drosophila melanogaster with 3 samples.

How the data were processed

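RNA of adult Drosophila melanogaster males was compared on 3 spotted 2-colour cDNA arrays of the Canadian Drosophila Microarray Center. Per the labels, each array held wild-type w1118 RNA in channel 1 with Cy3 and RNA of homozygous kep1 mutants in channel 2 with Cy5. The dyes were not swapped on any array, so a dye effect specific to a probe cannot be separated from genotype. The direction of every ratio rests on the channel numbers in the labels, since the scanner columns name channels and not dyes. Per the labels' protocols, total RNA was extracted with Trizol and a column. The design text places it in heads of males aged 3 to 4 days and gives 3 independent RNA samples, while the source labels name only male RNA. Replicate numbers follow the order of the records and carry no pairing beyond the array itself.

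The deposited scanner tables hold a foreground intensity, a local background intensity and the SD of that background for each spot and channel, on a linear scale and not normalized, per the file headers. The image software was not given in the sources used here. A deposited table of log2 values for the same arrays equalled log2 of the channel 2 over the channel 1 foreground intensity, with no background subtraction and no centring, at 27648, 24779 and 27616 spots of arrays 1, 2 and 3, with a largest difference of 5.3e-05. Its medians were -0.08, -0.20 and -0.04, and it was empty at 0, 2869 and 32 spots. Subtracted and ratio columns that the submitters added to 1 table were not used here.

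Each array had 27648 spots in 48 print-tip blocks, of which 878 were controls, 1734 were blank and 1548 carried a PCR product marked as failed. The other 23488 spots held 11744 probes in duplicate. Spots marked to be ignored (22, 76 and 26 on arrays 1, 2 and 3) were left out. Gene names came from the CG numbers in the scanner tables, updated through an NCBI RefSeq gene table of the Release 6 plus ISO1 MT assembly, which was used only for names, chromosome and gene order. A symbol was found for 10453 probes (546 of them through an older CG number) and none for 1291, which keep the identifier of the array layout. Among 10397 probes named in both layouts, 21 were named as different genes. The table lists kep1 as qkr58E-3.

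Background was corrected with normexp (offset 50) and ratios were normalized within each array by loess, with control, blank and failed spots at weight 0, in limma 3.58.1 under R 4.3.3. No scaling between arrays was applied. Duplicate spots were averaged. A probe was tested if at least 1 channel exceeded its local background by 2 background SDs on at least 2 of the 3 arrays, which 11733 probes of 9162 genes did. limma fitted the mean log2 ratio of mutant over wild type against 0, with empirical Bayes variances and a two-sided test, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 ratios are given as mean ± SD with n = 3 arrays. No label says how the flies behind the 3 RNA samples were reared or pooled, so the p-values measure the spread between these samples. The number of arrays limits the precision, and the prior variance carried only 2.33 degrees of freedom.

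Gene groups were 25 lists fixed before the data were examined, tested on 9160 genes, each represented by its brightest probe, with camera in limma (preset inter-gene correlation 0.01, at least 5 measured members, adjusted over the lists). camera with an estimated correlation, and fry, were alternatives. Older names placed 2 genes, Sam-S among the ribosomal proteins and Idh3a in oxidative phosphorylation, in lists to which they do not belong by function. Genes named in the text were fixed by rule: kep1 and its relatives, the 12 named genes per direction with the largest ratios among those past the threshold with 1 sign on all arrays, open places filled by the smallest unadjusted p and given as values only, and for each list up to 4 members past the threshold or else the 2 with the largest ratios of 1 sign. white, also in the rule, was not analysed here. Any other gene named was chosen after its values were seen.

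Alternatives fixed before the data were examined were no or plain background subtraction, print-tip loess, median centring, scale normalization between arrays, the deposited log2 table with its medians removed, no filter and a stricter filter on dim probes, an intensity trend with robust variances, a threshold of 0.1, the mean of all probes of a gene in the list tests, and leaving out each array. A filter on the 95th percentile of the blank spots was added after seeing the data.

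The steps were tested on simulated data with the real brightness and backgrounds, with variances drawn from the prior fitted to these arrays. For the mutant against wild-type comparison, with 11731 probes, 90.0% of 100 probes changed 2-fold and 98.0% of 100 changed 4-fold were called in the right direction, and 17 unchanged probes were called. A list shifted by -0.8 was recovered by camera at the preset correlation (adjusted p = 1.77e-44) and missed with an estimated correlation (adjusted p = 0.747) and by fry (adjusted p = 0.0831), and no unshifted list was called by any of these. The changed probes were drawn only from probes brighter than the blank spots and outside the fixed lists. Many true changes also ease the Benjamini-Hochberg adjustment, so these shares do not give the sensitivity on the real arrays. The simulated errors were independent between probes, which those of real arrays are not.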

Results

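Transcript levels in homozygous kep1 mutant males were set against those in w1118 wild-type males of Drosophila melanogaster, in a study of the cell division and behaviour of flies lacking Kep1. Kep1 is an RNA-binding protein of the STAR family, whose members carry a KH domain and act in RNA processing. Each of 3 arrays compared 1 mutant RNA with 1 wild-type RNA, so each gene had 3 log2 ratios of mutant over wild type. The design text places the RNA in heads, while the source labels name only male RNA. The median foreground intensity of the probes lay between 226.5 and 306.7 in the 6 channels, against median local backgrounds of 0 to 21. Blank spots had median foregrounds of 0 to 173.1 and 95th percentiles of 113.2 to 444.5, and 31.9% to 80.2% of probes exceeded that level in a channel. Across probes, which are not independent replicates, the log2 ratios correlated with Pearson's r = 0.41 between arrays 1 and 2, 0.691 between arrays 1 and 3 and 0.476 between arrays 2 and 3.

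The kep1 probe (qkr58E-3, CG3584) had log2 ratios of -1.59, -1.35 and -2.13 on the 3 arrays, a mean of -1.69 ± 0.40 (SD, n = 3). It did not pass the threshold over all probes (limma adjusted p = 0.0726), but did when adjusted over the list alone, as the only one of 5 measured members of the STAR family. Its foreground intensity was 851.7, 864.6 and 1343.1 in wild type and 253.6, 240.3 and 227.9 in the mutant, and the mutant value exceeded the 95th percentile of the blank spots on 1 array. The other members were how (0.10 ± 0.05), a regulator of muscle and glial RNA, qkr54B (0.12 ± 0.14), qkr58E-1 (0.13 ± 0.22) and qkr58E-2 (-0.02 ± 0.12), none past the threshold. The sign of qkr58E-2 changed with the normalization.

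Over all 11733 probes, 17 changed between mutant and wild type, with 8 higher and 9 lower in the mutant, each with the same sign on all 3 arrays. Of these, 12 had a gene symbol, and 4 of those genes rose while 8 fell. The largest rise with a symbol was that of CCHa2, which encodes the peptide hormone CCHamide-2, at 1.59 ± 0.15 on the log2 scale, or 3.02-fold (limma adjusted p = 0.0287). Acat1, an acetyl-CoA acetyltransferase, rose 2.11-fold (1.07 ± 0.07), sepia (se), which acts in the synthesis of the red eye pigments, rose 2.04-fold (1.03 ± 0.09), and the phosphatase gene hzg rose 1.83-fold (0.87 ± 0.01), with limma adjusted p-values of 0.0303, 0.0349 and 0.0349.

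The largest falls were those of the alpha-amylase genes Amy-d (-2.02 ± 0.15) and Amy-p (-1.90 ± 0.27), which encode starch-digesting enzymes and were 4.06-fold and 3.73-fold lower. These are near-identical copies whose cDNA probes can bind either transcript, so the values are uncertain for each gene alone. pastrel (pst), known for its part in resistance to a picorna-like virus, fell by 1.81 ± 0.20 on the log2 scale. exuperantia (exu), which acts in spermatogenesis and in RNA localization in the egg, stood at -1.68 ± 0.24, and loopin-1, a leucyl aminopeptidase of sperm, at -1.65 ± 0.21. As for the gut and testis lists below, body tissue in the wild-type RNA was not excluded for the amylase genes, exu and loopin-1. The lysosomal alpha-mannosidase gene LManVI (-1.56 ± 0.11), the chitin deacetylase gene Cda5 (-1.20 ± 0.07) and CG1324 (-0.96 ± 0.07) completed the 8, with limma adjusted p-values from 0.0287 to 0.0373 over all of them.

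The other 5 probes past the threshold had no gene symbol in the table used, and were named here after their values were seen. The largest change of all 17 was on a probe that the array layout annotates as the retrotransposon springer (TE20317), 11.7-fold higher in the mutant at 3.55 ± 0.40 (limma adjusted p = 0.0287). No array separated the kep1 genotype from other differences between the 2 strains. This and the other changes therefore cannot be assigned to the loss of kep1 alone. CG11538 rose by 2.38 ± 0.36, clone LP10041 by 1.44 ± 0.12 and clone GM08252 by 1.14 ± 0.01 on the log2 scale, while clone SD04061 had a ratio of -1.52 ± 0.18.

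**Figure D1:**
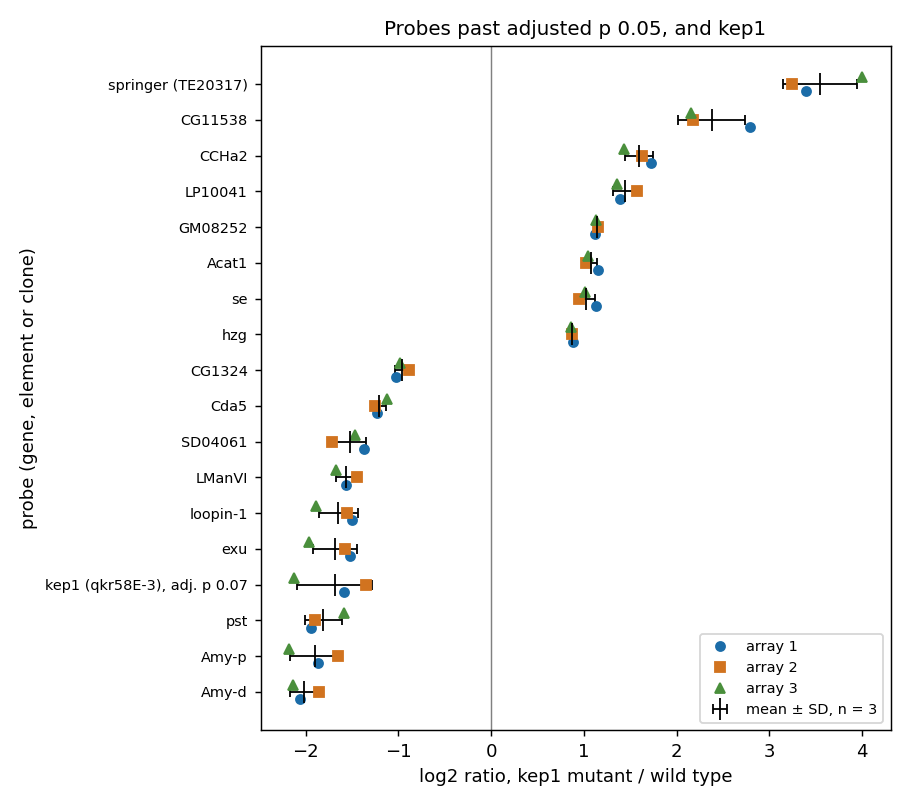
Log2 ratios of kep1 mutant over wild type (horizontal axis) for the 17 probes past the threshold and for kep1 (vertical axis), with 1 symbol per array and black bars for mean ± SD (n = 3). All 3 arrays lie on the same side of 0 for every probe, from -2.02 for Amy-d to 3.55 for springer, and kep1, at -1.69, is shown for reference with an adjusted p of 0.0726.

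At an adjusted p under 0.1 there were 253 probes, and at an unadjusted p under 0.05 there were 1814, of which 729 were higher and 1085 lower. The same sign on all 3 arrays was seen for 38.9% of probes, where chance gives 25%. A dye effect specific to a probe would also repeat in sign on these arrays, since no dyes were swapped. No probe passed in limma when array 1 or array 3 was left out (1333 and 1193 probes at an unadjusted p under 0.05) or after scale normalization between arrays (1830), and 100 passed without array 2. With median centring 25 probes were higher and 45 lower, and with the deposited log2 values 121 were higher and 302 lower.

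Several genes with the same sign on all arrays lay just outside the threshold, and their values follow without a call. On the higher side these were CG9360 (1.98 ± 0.39), the lens protein gene Crys (0.96 ± 0.16), lncRNA:CR32553 (0.83 ± 0.14), the chitinase gene Cht5 (0.82 ± 0.16), the ultraviolet opsin gene Rh4 (0.81 ± 0.12), CheA75a (0.71 ± 0.02) and CG10184 (0.62 ± 0.01), with limma adjusted p-values from 0.0557 to 0.0726. The actin-filament gene sals stood at 1.80 ± 0.41 on 1 probe, but at 0.13 on its other probe. On the lower side were LManV (-1.15 ± 0.19), a second alpha-mannosidase gene, Mybbp1A (-1.03 ± 0.14), CG13506 (-0.80 ± 0.10) and CG10912 (-0.71 ± 0.06), with limma adjusted p-values from 0.0557 to 0.0617.

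Genes for digestive enzymes of the gut were lower in the mutant channel as a group, although the design text places the RNA in heads. Body tissue in the wild-type RNA, a dye effect and the kep1 genotype were not told apart as causes. Of 27 measured members 2 fell over all genes tested (Amy-d and Amy-p), and 20 fell when adjusted over the list alone, with none higher. The median log2 ratio was -0.73, and 22 members were below 0 on all 3 arrays. Among members named after their values were seen, the serine protease genes Jon65Aiii (-2.19 ± 0.61) and alphaTry (-1.71 ± 0.97) had large ratios that differed between arrays, with alphaTry at -1.92, -0.65 and -2.55. camera in limma placed the list below other genes (adjusted p = 2.86e-11), a call that was lost with an estimated correlation (adjusted p = 0.865 with an estimated correlation). The estimated correlation between members was 0.179, against the preset 0.01, so the preset p-value may be too small. With an estimated correlation camera also missed the simulated list shifted by -0.8, so its failure to call a list decides little. The same limits hold for the lists below.

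Markers of the testis and of the accessory gland, the organ that makes seminal fluid proteins, were also lower in the mutant channel as a group. The causes left open for the gut list stay open here too. The median was -0.54 over 23 members. None passed over all genes in limma (15 were lower at an unadjusted p under 0.05 and 0 higher), and 10 fell when adjusted over the list alone. The seminal fluid protein gene Acp36DE stood at -1.43 ± 0.90 and Mst57Da at -1.39 ± 0.82. camera in limma gave the list an adjusted p of 2.68e-06, against an adjusted p of 0.865 with an estimated correlation. The size of the shift differed between arrays, with list medians of -0.77, -0.20 and -0.53, as it did for the gut list, with -0.66, -0.56 and -0.996.

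Transcripts that are abundant in females differed between the arrays. The yolk protein gene Yp1, named after its values were seen, had log2 ratios of -2.54, 2.96 and -0.78 on arrays 1, 2 and 3. Yp3 had 0.78, 2.39 and 0.64, a mean of 1.27 ± 0.98, and fit, a female-enriched transcript of the head fat body, had 0.31, 2.93 and 1.17, a mean of 1.47 ± 1.33, none past the threshold in limma. The female marker list did not stand apart from other genes (camera in limma, adjusted p = 0.524). Its 8 measured members were fit, Fst, Yp1, Yp2, Yp3, bcd, osk and yl. None of the eggshell genes set for the list was measured, so the test does not cover them.

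**Figure D2:**
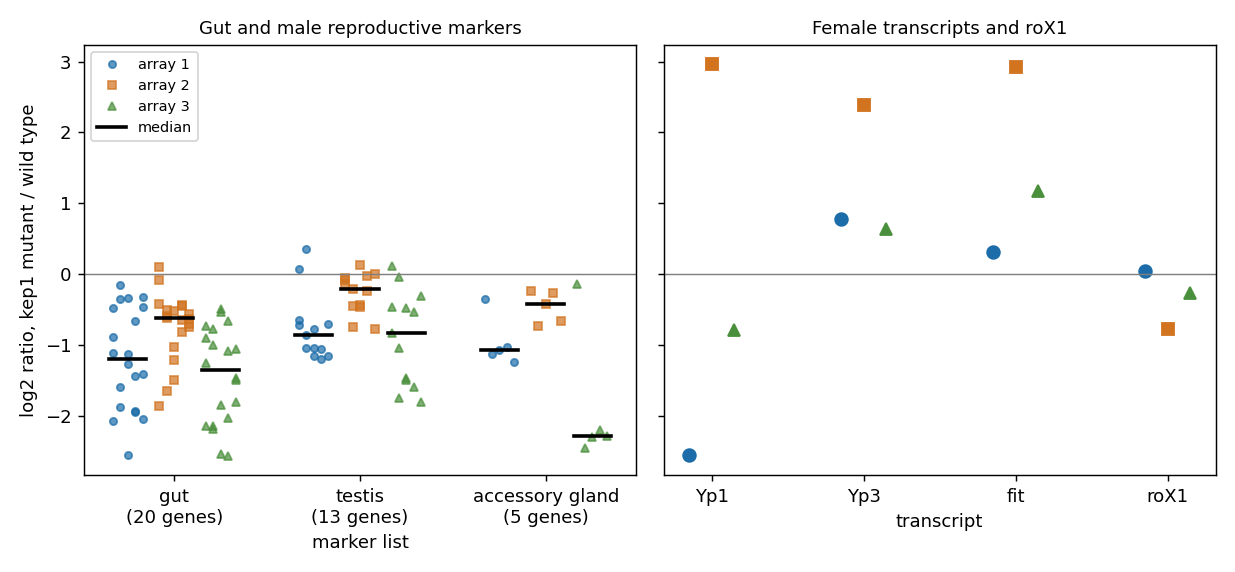
Log2 ratios of kep1 mutant over wild type (vertical axis) on each array for gut, testis and accessory gland genes brighter than blank spots (left, 1 point per gene, black bars at the medians) and for Yp1, Yp3, fit and the male-specific RNA roX1 (right, 1 point per array). The accessory gland median is -2.28 on array 3 and -0.41 on array 2, and Yp1 ranges from -2.54 on array 1 to 2.96 on array 2.

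Oxidative phosphorylation genes had a median of -0.13 over 73 members. None passed over all genes in limma (20 were lower and 0 higher at an unadjusted p under 0.05), and 6 fell when adjusted over the list alone. ND-39 of complex I stood at -0.54 ± 0.20 and ATPsynbeta of the ATP synthase at -0.44 ± 0.10. The name patterns of this list also took in paralogs whose symbols add an L. Among these, named after their values were seen, were SdhAL (-0.41, among those 6) and COX4L (-0.38), but also ND-24L (0.07) and ND-B14.5AL (0.08). In which tissues the paralogs are expressed was not examined, and the list was not tested without them. camera in limma called the list lower (adjusted p = 3.09e-06), but not with an estimated correlation, as an adjusted p of 0.865 with an estimated correlation shows. The medians were -0.10, -0.06 and -0.20 on arrays 1, 2 and 3, smallest in size on array 2, as in the gut and testis lists. Whether this shift shares a cause with those lists was not tested.

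Heat shock and chaperone genes had a median of -0.25 over 20 members, with 0 past the threshold over all genes in limma, 4 lower and 0 higher at an unadjusted p under 0.05, and 3 that fell when adjusted over the list alone. The co-chaperone gene starvin (stv) stood at -1.51 ± 0.40 on its brightest probe but at -0.03 ± 0.28 on its other probe, and the mitochondrial chaperonin gene Hsp60C stood at -0.85 ± 0.43. camera in limma called the list lower (adjusted p = 0.00121, and adjusted p = 0.865 with an estimated correlation). The medians were -0.01, -0.61 and -0.08 on arrays 1, 2 and 3, and without array 2 the list did not pass (median -0.03, adjusted p = 0.629). Among members named after their values were seen, Hsp70Aa had 1.32, -2.63 and 0.27 and Hsp68 had 0.74, -2.40 and 0.04 on these arrays. By contrast, stv had -1.865, -1.073 and -1.595 on its brightest probe.

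Neuronal and synaptic genes were called slightly higher by camera in limma, with a median of 0.06 over 32 members (adjusted p = 0.0438, and adjusted p = 0.865 with an estimated correlation). No member passed over all genes or when adjusted over the list alone in limma, and 5 were higher and 0 lower at an unadjusted p under 0.05. The potassium channel gene slo stood at 0.72 ± 0.35 and the synaptic vesicle priming gene unc-13 at 0.59 ± 0.29, but their other probes stood at 0.08 ± 0.52 and 0.16 ± 0.11. The array medians were 0.08, -0.07 and 0.15, and the call was lost with any of 4 other normalizations or background corrections, without array 1 or 3, and with the mean of all probes of a gene.

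Among phototransduction genes, 4 of 32 rose and 1 fell when adjusted over the list alone, and none passed over all genes in limma (5 higher and 2 lower at an unadjusted p under 0.05). The opsin genes of the R7 and R8 photoreceptors Rh4 (0.81 ± 0.12) and Rh6 (0.58 ± 0.16) were the members with the largest ratios. The list did not pass in camera (median 0.08, adjusted p = 0.0968), but did without array 2 (median 0.18, adjusted p = 2.60e-04) and with the deposited log2 values (median 0.14, adjusted p = 0.00442). Glial markers had a median of 0.08 (adjusted p = 0.0968, and 0.0483 without array 2), with the glutamate transporter gene Eaat1 at 0.34 ± 0.04 and the glutamine synthetase gene Gs2 at 0.21 ± 0.07. Neuropeptide genes had a median of 0.05 (adjusted p = 0.0968), with Ms at 0.24 ± 0.19 and Mip at -0.23 ± 0.18. In the eye pigment list 1 of 22 members, sepia, rose over all genes, and the list as a whole did not pass (median 0.03, adjusted p = 0.218). Circadian clock genes had a median of 0.03 (adjusted p = 0.524), with Pdp1 at -0.19 ± 0.16 and takeout (to) at 0.49 ± 0.53.

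Lists chosen for the reported parts of Kep1 in cell division, cell death and RNA processing did not pass in camera in limma. Cytokinesis genes had a median of 0.02 over 31 members (adjusted p = 0.468), with the profilin gene chic at 0.22 ± 0.18 and Rho1 at 0.18 ± 0.06 (0.0040 ± 0.20 and 0.04 ± 0.06 on their other probes). Apoptosis genes and caspases had a median of 0.0039 over 15 members (adjusted p = 0.945), with Diap2 at -0.21 ± 0.17 and Dcp-1 at -0.14 ± 0.06. Splicing and RNA processing genes had a median of -0.01 over 37 members (adjusted p = 0.949), with snRNP-U1-70K, a core protein of the U1 particle, at -1.51 ± 0.59 on its brightest probe and -0.02 ± 0.10 on its other probe, and Rbp9 at 0.58 ± 0.16. Of these 3 lists, only the splicing list had members past the threshold adjusted over the list alone, 1 higher and 1 lower.

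Among 13 antimicrobial peptide and effector genes none passed over all genes in limma (1 higher and 2 lower at an unadjusted p under 0.05), and 1 rose and 2 fell when adjusted over the list alone, with drosomycin (Drs) at 0.47 ± 0.19 and its relative Drsl5 at -0.97 ± 0.31, and the list did not pass in camera (median -0.06, adjusted p = 0.268). Immune signalling and recognition genes had a median of 0.02 over 31 members (adjusted p = 0.279), none of which passed in limma over all genes or adjusted over the list alone (3 higher and 2 lower at an unadjusted p under 0.05), with the thioester proteins Tep4 at 0.56 ± 0.33 and Tep2 at 0.43 ± 0.17.

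Among 35 fat body and metabolism genes none passed over all genes in limma (5 higher and 7 lower at an unadjusted p under 0.05), and 3 rose when adjusted over the list alone. The storage protein gene Lsp2, 1 of these 3, stood at 2.71 ± 0.97, or 6.57-fold, with ratios of 3.83, 2.13 and 2.18, but did not pass over all genes (limma adjusted p = 0.0959), and Fbp2, which passed neither way, stood at 0.96 ± 0.61. The list itself had a median of 0.03 (camera in limma, adjusted p = 0.524) and passed with the deposited log2 values (median 0.07, adjusted p = 0.0446). Muscle genes had a median of -0.10 (adjusted p = 0.0968), with flightin (fln) at -1.57 ± 0.55 and TpnC4 at -1.14 ± 0.70, and the muscle list passed without array 2 (median -0.15, adjusted p = 6.40e-04) and with the mean of all probes of a gene (median -0.08, adjusted p = 0.0455). Male head-enriched and courtship genes (median -0.0019, adjusted p = 0.679) included the odorant-binding protein gene Obp99b at 1.62 ± 0.55, with a second probe at 0.94 ± 0.22, and Cyp4d21 at -0.81 ± 0.63, with a second, dimmer Cyp4d21 probe at -0.03 ± 0.04. Of the 16 members of that list 3 rose and 2 fell when adjusted over the list alone, and Cyp4d21 did not pass. Odorant-binding and chemosensory genes (median -0.02, adjusted p = 0.854) included Obp51a at -1.29 ± 0.66, and 2 of 39 members rose and 1 fell when adjusted over the list alone.

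The remaining lists did not pass in camera in limma with all 3 arrays. Cytochrome P450 genes had a median of -0.01 over 82 members (adjusted p = 0.947), with Cyp4g1 at -1.46 ± 0.79 and Cyp309a2 at 1.31 ± 0.64. Glutathione and glucuronosyl transferases had a median of 0.0098 over 49 members (adjusted p = 0.524), with Ugt35B1 at -2.01 ± 0.72 and Ugt50B3 at -0.91 ± 0.85. When adjusted over the list alone, 1 transferase rose and 3 fell. The mutant channel of Ugt35B1 was above local background on 1 array and above the blank spots on 0, so its ratio is limited by the floor, and it was -3.06 without background subtraction (limma adjusted p = 0.00416). Other dim genes also had ratios that grew and passed the threshold in limma under another background correction. Among them were Cyp309a2 (2.01), fit (2.13) and Tep4 (1.19) without background subtraction and Fbp2 (1.57) with plain subtraction. The ratio of fit was 0.74 without array 2. Ribosomal protein genes had a median of -0.02 over 79 members (adjusted p = 0.524), with RpS2 at -0.32 ± 0.19 and RpS3 at -0.31 ± 0.13 (-0.11 ± 0.19 on its other probe). Without array 2 the ribosomal list passed (median -0.07, adjusted p = 0.00777). Sex determination and dosage compensation genes had a median of 0.03 over 13 members (adjusted p = 0.468), with msl-3 at 0.34 ± 0.17, and the STAR family had a median of 0.10 (adjusted p = 0.928). The median, the mean and the test differed in sign for the STAR, female marker, male head-enriched, chemosensory, transferase and apoptosis lists, so no direction is given for them.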

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

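The filter on blank spots was chosen after seeing the data, and the other alternatives before. Against the 17 probes called (8 higher, 9 lower), there were 434 without background subtraction (116 higher, 318 lower), 389 with plain subtraction (101 and 288), 70 with median centring (25 and 45), 423 with the deposited log2 values (121 and 302), 35 with both channels above background on all arrays (13 and 22), 358 with the filter on blank spots (96 and 262), 280 with an intensity trend and robust variances (71 and 209), and 253 at an adjusted p under 0.1 (92 and 161). There were 0 after scale normalization, in either direction, with 1830 at an unadjusted p under 0.05 in limma. Leaving out 1 array gave 0 to 100 probes, 0 to 16 higher and 0 to 84 lower, with 0 when array 1 or 3 was left out. Fewer probes tested or fewer arrays are part of the filters and the left-out arrays, and the cause of the other differences was not tested. All 12 named genes past the threshold remained past it in every alternative run for single genes except scale normalization and leaving out array 1 or 3, and their sign held in every one of these alternatives. The kep1 probe passed in 6 of 13 alternatives, with ratios from -1.98 to -1.47 and limma adjusted p-values from 9.07e-04 to 0.322. Of the 58 named genes not past the threshold, kep1 among them, 36 passed under at least 1 alternative.

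The 5 lists called by camera became 0 with an estimated correlation and 0 with fry (0 and 2 lists at an unadjusted p under 0.05 in limma), and 4 to 8 when 1 array was left out, with 8 without array 2, where phototransduction, muscle, ribosomal and glial lists passed and the heat shock list did not. The fry counts are for shifts in 1 direction. The mixed form of fry, for changes of either sign, passed most of the lists, so a pass alone sets no list apart. Its adjusted p was 4.03e-05 for chemosensory and 0.00147 for splicing genes. It was also 0.0078 for eye pigment, 0.0095 for cytochrome P450 and 0.029 for transferase genes. For cytokinesis and apoptosis genes it was 0.308 and 0.675. The lowest correlation between arrays fell from 0.41 to 0.233 with the deposited log2 table, whose values are neither loess-normalized nor background-corrected, and the cause was not tested. No list past the threshold changed sign. The sign of the test changed 31 times among 7 of the 20 other lists, all with adjusted p-values over 0.2, and the cause was not tested. The list medians in those cases follow. For cytochrome P450 they were -0.010 without background subtraction, -0.052 with plain subtraction, 0.0059 with median centring, -0.0066 with the deposited table, -0.051 with the stricter filter, -0.032 with the filter on blank spots and -0.014 with the mean of all probes. For the STAR family they were 0.102, 0.105, 0.101, 0.162 and 0.098 for the first 4 of these and for the blank filter, and 0.098 with fry. For splicing they were 0.0056 with plain subtraction, -0.012 with print-tip loess, -0.011 after scale normalization and 0.025 with the deposited table. For apoptosis they were 0.028 with plain subtraction, 0.00091 with print-tip loess and 0.020 with the stricter filter. For ribosomal proteins they were -0.019 with plain subtraction and 0.030 with the deposited table, and for chemosensory genes -0.019 with fry. The sign of qkr58E-2 changed to 0.022 without background subtraction, 0.0021 with print-tip loess and 0.028 with the deposited table.

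When 1 array was left out, the ranges for what changed sign were -0.066 to 0.044 for qkr58E-2, -0.029 to -0.0048 for the median of apoptosis genes, -0.022 to -0.0074 for cytochrome P450, -0.034 to 0.041 for fat body genes, -0.069 to 0.028 for ribosomal proteins, -0.028 to 0.023 for splicing and 0.044 to 0.072 for the STAR family.

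Signal over background limits these results, since only 6076 probes exceeded the 95th percentile of the blank spots in at least 1 channel on 2 or more arrays. A ratio of a probe near that level, such as kep1 in the mutant channel, is pulled toward 0.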

Other observations

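The tests of whole-body tissue, of a dye effect, of brightness and of sign patterns were chosen after the results were seen, and those of roX1 and of duplicate spots before. The test of the neighbours of kep1 was chosen before, but the use of the interval of its odds ratio was added after its result was seen. Among genes outside the fixed lists with low ratios on arrays 1, 2 and 3, named after their values were seen, the peptidase gene CG12374 had -3.18, -1.04 and -3.17, yip7, a serine protease gene, had -1.95, -0.97 and -2.03, and Alp4, an alkaline phosphatase gene, had -1.68, -1.19 and -1.78. Besides springer, the array held 2 more probes annotated as transposable elements, of which TE19206 stood at 1.05 ± 0.36 (limma adjusted p = 0.0959) and the HMS-Beagle pol probe at 0.01 ± 0.18.

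Genes with an unadjusted p under 0.05 in limma leaned to the lower side on the large autosome arms but not on the X chromosome. There were 87 higher and 184 lower genes on 2L, 93 and 193 on 2R, 84 and 172 on 3L and 127 and 251 on 3R, against 118 and 109 on X and 9 and 3 on chromosome 4. The share of genes at that p was 15.6% on X and 14.5% to 16.7% on the 4 large autosome arms. The difference in direction between chromosomes was not tested.

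Taking the ratios of 1 array at a time with the opposite sign gave at most 0 probes past the threshold, against 17 in the real arrangement. Of 4 such patterns 1 gave as many, the real one, and 4 patterns are too few for a share under 0.05.

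The gut, testis and accessory gland genes brighter than blank spots (38 genes) had medians of -1.05, -0.48 and -1.35 on arrays 1, 2 and 3. A brightness bias is argued against by a median of -0.943, below the lowest of 10000 random lists of like brightness (-0.211). Body tissue left on wild-type heads in one whole-body proportion may lower these genes. The medians of the 3 tissues lay 1.45 apart on array 3 (accessory gland -2.28, testis -0.83), more than the mean SD of 0.773 within tissues. They lay 0.418 apart against 0.335 on array 2, but 0.33 against 0.515 on array 1. These gaps cannot decide the question, since carried-over RNA need not shift all log2 ratios equally. A ratio also depends on the level in the mutant channel and on the floor, and the accessory gland median rests on 5 genes. A dye effect fixed to these probes also stays open, since no dyes were swapped and the medians, 0.866 apart at most, were all below 0. Tissues left in unequal amounts, and an effect of the kep1 genotype itself, were not tested and stay open, and how many of these genes the head also expresses was not examined.

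On array 2 the female transcripts Yp1 (2.96), Yp3 (2.39) and fit (2.93) were high in the mutant channel. Spot artifacts are argued against, since duplicate spots of these probes and of Yp2 differed by at most 0.299 there. Female heads in the mutant extract of array 2 may account for this. The male-specific RNA roX1 stood at -0.775 on array 2 (duplicate spots 0.528 apart) against 0.05 and -0.26 on arrays 1 and 3. Such a fall on array 2 alone is not particular to roX1, so it cannot settle the question. Among splicing genes, named after their values were seen, Hrb27C had -0.03, -1.25 and 0.22 on arrays 1, 2 and 3. In the same list mub had 0.15, -0.83 and 0.18. The probe of fit was above the blank spots on 1 array in wild type and 2 in the mutant. Other values are mixed: male-enriched takeout was at 1.09 and the dosage compensation gene msl-2 at 0.21 on array 2, male-enriched Cyp4d21 was at -1.06 there but also at -1.27 on array 3 (-0.09 on array 1), and the yolk protein gene Yp2 was at 0.13, on a probe under the level of blank spots in the mutant channel of all arrays. Yp1 at -2.54 on array 1 is not covered by this hypothesis, and a genotype effect on these transcripts was not tested.

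Strain differences in the chromosome segment around kep1 may change neighbouring genes, and 19 of the 100 measured genes nearest to kep1 had an unadjusted p under 0.05 (14 lower, 5 higher), against 15.6% of 9059 other genes. The odds ratio was 1.27 with a 95% interval of 0.726 to 2.12 (Fisher's exact test, two-sided, p = 0.333), so an enrichment was neither shown nor excluded. CG13506 (-0.80 ± 0.10) and CG2921 (-0.68 ± 0.19) had the smallest p-values of that segment. A genotype effect on these genes was not tested apart from their position.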
